A study of Arabidopsis thaliana with 16 samples.

How the data were processed

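Poly(A) RNA was measured by sequencing in 16 libraries of Arabidopsis thaliana, 4 from each of 4 genotypes: wild type Col-0 (WT), the ckx3 ckx5 double mutant, the strigolactone receptor mutant d14-7 and the scl28 mutant. The tissue was the rosette region of plants whose bolt was still shorter than 1 cm, with leaves, roots and the elongated upper stem cut away, so that the lower stem and its axillary meristems remained. Per the labels, each library came from a pool of 2 to 3 plants, 5 pools were collected per genotype, and the 4 with the highest RNA integrity were sequenced. WT, ckx3 ckx5 and d14-7 plants were harvested 23 days after sowing and scl28 plants 25 days after sowing, all between 9 and 11 in the morning under a cycle of 16 h light and 8 h dark. Genotype and harvest day therefore cannot be separated for scl28. Libraries were made with a NEBNext Ultra RNA kit, which does not mark strand, so that reads of a gene and of an overlapping or antisense partner cannot be told apart.

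The authors deposited a table of estimated counts for 41671 transcript models, already in whole numbers, so that no rounding was needed before the count tests. Total counts ran from 24334925 to 36735056 per library, and these differing totals showed that the counts had not been scaled. The deposited normalized table holds a signal in which each count is divided by a factor close to 1 value per library, and 98.04% of these ratios lay within 1% of the median of their column. TAIR10 and DESeq2 are named without a version in the submitters' processing notes. The aligner, the tool that estimated the counts, the strand setting and any filter are not given in the sources used here. The normalized table was used only for this check of scaling.

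Counts of the transcript models were summed to 33602 loci, of which 5885 have several models. Gene symbols and coordinates came from the RefSeq annotation of assembly TAIR10.1, in which 32835 of the loci were found and 10654 of them carry a symbol. Loci without a symbol are named by their locus identifier. All 16 columns were used. No 2 libraries of the same group held counts that agreed within sampling noise: the chi-square statistic per gene between libraries of 1 group ranged from 4.75 to 97.73. The organelle genomes took little of the total, with 0.028% to 0.06% of counts on chloroplast loci and 0.005% to 0.013% on mitochondrial loci.

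Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with TMM normalization and the filterByExpr filter, which left 20947 loci. All 16 libraries entered 1 model with 4 genotype means and no other term, so that the groups shared 1 estimate of spread per locus, and the common dispersion was 0.016. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene is said to have risen, fallen or changed where its edgeR adjusted p was under 0.05. Log2 fold changes are those of the model, each with its standard error, and levels are CPM (counts scaled to library size) with the standard deviation over libraries. Log2 CPM values used a prior count of 2. The p-values measure the spread between separately pooled samples of plants.

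The choices of groups, tests, lists, named genes and alternative settings were made before the data were examined. There were 22 lists of genes with 366 members together with the 4 targeted genes, and all members were kept. For 12 members the annotation gives no name to compare, and 2 genes stand in 2 lists. The lists cover the strigolactone and karrikin pathway, bud dormancy, carbon starvation, type-A response regulators, other cytokinin-induced genes, cytokinin synthesis and breakdown, auxin response, auxin transport and synthesis, gibberellin, abscisic acid, G2/M and S phase genes, CDK inhibitors, meristem genes, flowering genes, salicylic acid defence, jasmonate, leaf photosynthesis, root, xylem, wounding and touch, and the circadian clock. Leaf, root, xylem and flowering markers stand for other tissue in the sample, and wounding and clock genes for handling and hour of harvest. For each list the measured members that rose or fell over all genes tested were counted, and again with the p-values adjusted over the list alone. Lists with at least 5 measured members were tested with camera from limma 3.58.1, which compares a list with all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists by Benjamini-Hochberg. Below, an adjusted p of a list is that of camera with the preset correlation unless an estimated correlation is named. With an estimated correlation the calls that held were bud dormancy and auxin transport in d14-7, salicylic acid defence and the clock in scl28, and the clock between scl28 and the libraries labelled ckx3 ckx5.

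Named genes were chosen by rule. The rule took the 4 targeted genes. It took the 6 largest rises and 6 largest falls among called genes with a symbol, a mean log2 CPM of at least 2 and no overlap between the libraries of both groups. It also took up to 3 members with the smallest p of each list that held a called gene. For pairs of comparisons it took the 5 genes per direction with the largest smaller change. This gave 92 genes for ckx3 ckx5 against WT, 90 for d14-7, 92 for scl28 and 73 for scl28 against ckx3 ckx5. For pairs of comparisons SWEET10, AT2G47880, AT3G05730, AT1G66100, IAA32, AT5G52710 and AT5G45180 met the rule but are not described, because single libraries decided their calls or sizes. Further members of these lists are named where they complete a group. They were chosen after their values were seen.

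Overlaps between comparisons with the shared WT libraries were set beside the count that independent lists give, beside 20 simulations of unchanged groups against the same WT libraries, and beside all 6 ways of giving each comparison its own 2 WT libraries. The tests were first run on simulated counts for the 20947 loci with 50 genes changed at each of 4 sizes. A fold of 1.5 was recovered for 60% of genes for ckx3 ckx5 against WT, 50% for d14-7, 62% for scl28 and 60% for scl28 against ckx3 ckx5. Recovery in this order was 76%, 84%, 82% and 76% at a fold of 2, 94%, 98%, 94% and 94% at 4, and 98%, 98%, 98% and 100% at 8. Unchanged genes called numbered 5, 7, 9 and 8, but 4832 in 1 of the 20 simulations (ckx3 ckx5).

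The alternative settings were size factors of DESeq2 or upper-quartile factors in place of TMM, no filter, a stricter filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, only the compared groups in the model, the replicate number or the library number as a block, an adjusted p of 0.01, a fold of at least 2, and leaving out each library. Added after the data had been seen were tests on the transcript models, a mean of the leaf photosynthesis genes (leaf score) as a covariate, and the WT libraries taken 2 at a time. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Near-identical copies whose reads the counting could divide arbitrarily are CAB1, CAB2 and CAB3, the RBCS genes RBCS1B, RBCS2B and RBCS3B, KIN1 and KIN2, and the plant defensins PDF1.2, PDF1.2b, PDF1.2c and PDF1.3. Their single values are uncertain.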

Results

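The series asked how loss of the GRAS transcription factor SCL28, or of the cytokinin oxidases CKX3 and CKX5, changes gene expression in the rosette region from which rosette branches grow, beside WT and beside d14-7, a mutant of the strigolactone receptor. Its title states that mutation of SCL28 or of CKX3 and CKX5 suppresses rosette branching. Each of the 4 genotypes had 4 libraries, each from separately pooled plants. Library totals ran from 24334925 to 36735056 counts, and between 24269 and 28493 loci had at least 1 count. The 10 most abundant loci took 3.76% to 4.29% of the counts of a library. Below, a change is a log2 fold change ± its standard error with n = 4 libraries per group, and an edgeR adjusted p is that of the quasi-likelihood test with Benjamini-Hochberg adjustment.

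The 4 genotypes separated on the first principal components, which held 31.4%, 21.2% and 15.5% of the variance of log2 CPM. WT was the most spread group. Its libraries correlated with each other at 0.968 to 0.99 across genes, against 0.988 to 0.991 for the libraries labelled ckx3 ckx5, 0.987 to 0.989 for d14-7 and 0.984 to 0.99 for scl28. WT replicates 1, 2, 3 and 4 stood at -18.2, 5.8, 12.7 and 18.3 on the first component. Photosynthesis genes of the leaf followed this spread. The leaf score, which is the mean log2 CPM of these genes, was 10.83, 10.42, 10.06 and 9.87 in WT replicates 1 to 4. It lay at 9.93 to 10.21 in the libraries labelled ckx3 ckx5, 10.55 to 10.89 in d14-7 and 9.85 to 10.14 in scl28, so that WT spanned nearly the whole range of the mutants.

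**Figure D1:**
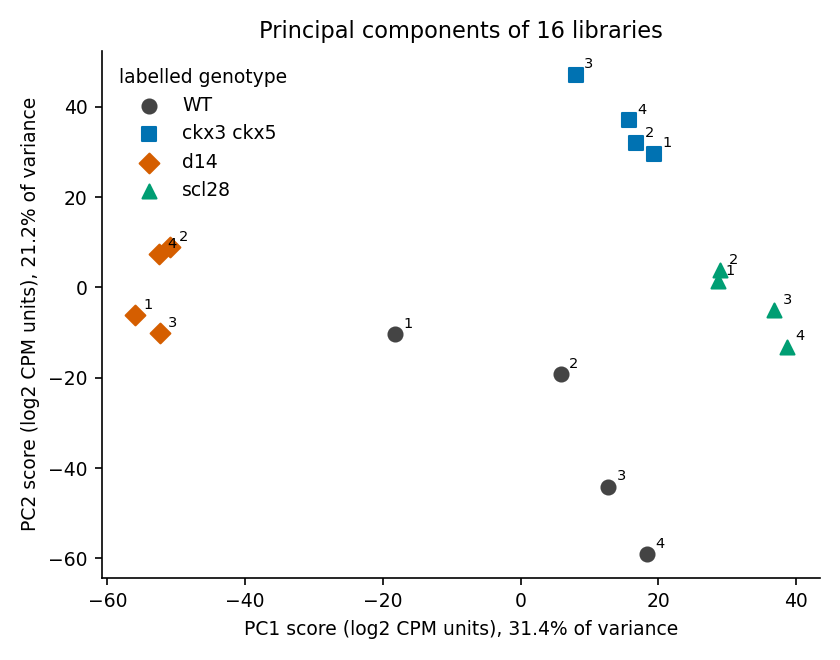
Position of the 16 libraries on the first and second principal components of log2 CPM over the 20947 tested loci, 1 point per library, coloured by genotype, with the percentage of variance on each axis. The WT libraries are the most scattered, from -18.2 to 18.3 on the first component, while the libraries of each mutant lie close together.

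The targeted genes were examined first in every library. SCL28 (chromosome 1, 23399112 to 23402176, minus strand, TAIR10.1) was at 15.5 ± 1.95 CPM (SD, n = 4) in scl28 and 36.5 ± 8.73 CPM in WT, a fall of -1.23 ± 0.15 with an edgeR adjusted p of 3.99e-05. D14 (chromosome 3, 1033579 to 1035237, plus strand) was at 30.5 ± 2.74 CPM in d14-7 and 41.2 ± 2.08 CPM in WT and fell by 0.43 (edgeR adjusted p = 0.000251). Transcript of both genes was thus still counted in their mutants, and the labels do not give the kind of lesion. CKX5 (chromosome 1, 28314458 to 28318375, minus strand) was at 2.83 ± 0.955 CPM in the libraries labelled ckx3 ckx5 and 3.33 ± 1.87 CPM in WT, which did not differ by edgeR (-0.23 ± 0.33, adjusted p = 0.634). CKX3 (chromosome 5, 23044839 to 23048292, minus strand) went against the label. It was at 1.73 ± 0.22 CPM in the libraries labelled ckx3 ckx5 and 0.339 ± 0.298 CPM in WT, a rise of 2.40 ± 0.51 with an edgeR adjusted p of 0.00201. The counts were low, at 58, 40, 65 and 54 in the 4 libraries labelled ckx3 ckx5 and 20, 15, 4 and 2 in WT. In scl28 and d14-7, CKX3 was at 0.478 ± 0.0797 and 0.425 ± 0.277 CPM. Against WT replicates 3 and 4 alone, CKX3 was also higher in d14-7 (2.35, edgeR adjusted p = 0.00526) and in scl28 (2.45, adjusted p = 0.00692). Because neither targeted gene was lower in them, these libraries are named by their label throughout, and every direction given for them rests on that label.

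Some targeted genes also differed in other genotypes. D14 fell in the libraries labelled ckx3 ckx5 to 28.1 ± 1.69 CPM (-0.55 ± 0.07, edgeR adjusted p = 1.37e-05) and was at 39.5 ± 1.32 CPM in scl28 (-0.06 ± 0.07, adjusted p = 0.563). SCL28 rose in d14-7 to 51.1 ± 6.67 CPM (0.49 ± 0.14, edgeR adjusted p = 0.015) and was at 43.7 ± 3.79 CPM in the libraries labelled ckx3 ckx5 (0.26 ± 0.14, adjusted p = 0.182). CKX5 rose in d14-7 to 7.71 ± 2.44 CPM (1.22 ± 0.32, edgeR adjusted p = 0.00783). The edgeR call for CKX5 in d14-7 was lost with the leaf score as a covariate (adjusted p = 0.149) and against WT replicates 1 and 2 alone (adjusted p = 0.154). That of SCL28 in d14-7 was lost without d14-7 replicate 2 (0.056), with only the 2 groups in the model (0.0581), with the leaf score (0.284) and against WT replicates 1 and 2 alone (0.212), and SCL28 passed in the libraries labelled ckx3 ckx5 without WT replicate 1 (0.0291).

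In the libraries labelled ckx3 ckx5, all 15 measured salicylic acid defence genes were lower than in WT, and all 9 clock genes had changed. PR1, a classical salicylic acid marker, fell by 2.82 (SE 0.39), and WRKY70, a transcription factor of the same response, fell by 1.85 (SE 0.11). The morning clock genes LHY and CCA1 changed by -3.61 ± 0.07 and -2.42 ± 0.07, while PRR5, which peaks later in the day, rose by 3.80 ± 0.18. Cytokinin-induced type-A response regulators were higher, with 6 of 8 past the threshold, among them ARR7 at 1.09 ± 0.31 and ARR15 at 1.01 ± 0.25. BRC1, which restrains bud outgrowth, rose by 0.65 ± 0.19 (replicate 4 within WT) and the strigolactone synthesis gene MAX4 by 1.89 ± 0.15. Of 20947 genes tested, 6205 changed by edgeR, 2853 up and 3352 down, and 1141 of them at least 2-fold (307 up, 834 down). The count was 3813 against WT replicates 1 and 2 alone.

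Cytokinin genes were examined because CKX enzymes break down cytokinin. The type-A response regulators rose as a list (6 of 8 rose, 0 fell, 6 adjusted over the list alone, median 0.76, camera adjusted p = 0.00215, adjusted p = 0.569 with an estimated correlation). ARR4, ARR5, ARR6 and ARR9 rose by 0.80 ± 0.17, 0.64 ± 0.13, 0.78 ± 0.16 and 0.73 ± 0.12, while ARR8 was at 0.10 and ARR16 at -0.07. Of the 9 other cytokinin-induced genes, the cytokinin receptor gene AHK4 (0.51 ± 0.10) and LBD3 (0.51 ± 0.16) rose and 0 fell, also 2 adjusted over the list alone (camera adjusted p = 0.389). The edgeR call of LBD3 was lost without WT replicate 3 (adjusted p = 0.0587) or 4 (0.0747) or ckx3 ckx5 replicate 2 (0.0613), and that of AHK4 on transcript models (0.508). Among 21 genes of cytokinin synthesis and breakdown, 2 rose and 5 fell, 9 adjusted over the list alone, and the list had no common direction (camera adjusted p = 0.769, median 0.01, mean -0.22). IPT7, which encodes an isopentenyltransferase of cytokinin synthesis, had 3 counts over these libraries and 76 in WT, 24.2-fold fewer for library size (95% counting interval 7.94 to 120). The breakdown genes CKX6 and CKX1 rose by 0.93 ± 0.09 and 0.35 ± 0.10, whereas CKX7 fell by 0.36 (SE 0.07).

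Genes of strigolactone and of bud dormancy went both ways in the libraries labelled ckx3 ckx5. Of 15 strigolactone and karrikin genes 4 rose and 4 fell, 8 adjusted over the list alone (camera adjusted p = 0.409). The synthesis genes MAX4 (1.89 ± 0.15) and MAX3 (1.25 ± 0.30) rose and so did SMXL8 (0.83 ± 0.10), a repressor of the pathway, while MAX1, a later synthesis gene, stood at -1.22 ± 0.13. Of the 9 bud dormancy genes 4 rose and 1 fell, 5 adjusted over the list alone (camera adjusted p = 0.0891). DRM1, DRM2 and the homeodomain gene HB40 rose by 1.62 ± 0.25, 1.99 ± 0.30 and 0.56 ± 0.18, and the histone gene HIS1-3 fell by 1.94 (SE 0.41). In replicate 4 HB40 (125 counts) and BRC1 (217) lay within WT (110 to 170 and 194 to 303). HB21, HB53 and NCED3 stood at 0.11 ± 0.29, 0.17 ± 0.28 and 0.09 ± 0.34. Of 17 carbon starvation markers 5 rose and 1 fell, 6 adjusted over the list alone (camera adjusted p = 0.137), with DIN10 at 2.22 ± 0.25 and EXL1 at -2.16 ± 0.37.

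Other hormone lists were mixed. In auxin response 3 of 13 genes rose and 0 fell, 3 adjusted over the list alone, with IAA1 at 1.37 ± 0.17 and IAA5 at 1.29 ± 0.29 (camera adjusted p = 0.0385, adjusted p = 0.754 with an estimated correlation). The camera call for auxin response was lost without WT replicate 1 (0.198), without ckx3 ckx5 replicate 4 (0.0672) and with the leaf score as covariate (0.144). Auxin transport and synthesis had 6 of 17 up and 4 down, 10 adjusted over the list alone (camera adjusted p = 0.225), with the auxin synthesis gene TAA1 at 0.69 ± 0.17 and the auxin carrier PIN3 at -0.49 ± 0.11. In the gibberellin list 6 of 16 rose and 2 fell, 9 adjusted over the list alone (camera adjusted p = 0.0201, adjusted p = 0.471 with an estimated correlation). The camera call for gibberellin was lost without WT replicate 1 (0.118) and with the leaf score as covariate (0.111). GA2OX1, which encodes an enzyme that inactivates gibberellin, rose by 2.46 ± 0.22, GA20OX2, of gibberellin synthesis, by 1.71 ± 0.30, and the gibberellin-responsive genes GASA4 and GASA6 by 1.31 ± 0.13 and 1.51 ± 0.16. Abscisic acid response had 4 of 24 genes up and 10 down, 14 adjusted over the list alone, with COR15A at 1.05 ± 0.14, HB12 at -0.98 ± 0.13 and the phosphatase gene HAB1 at -0.81 ± 0.07. Its camera adjusted p of 0.0486 (adjusted p = 0.764 with an estimated correlation) was lost without WT replicate 2 (0.0734), 3 (0.0658) or 4 (0.126), without ckx3 ckx5 replicate 3 (0.0942) or 4 (0.142), and with upper-quartile factors (0.0505), the stricter filter (0.0867) or only the 2 groups in the model (0.103).

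Some division genes were higher in the libraries labelled ckx3 ckx5. Of 25 G2/M genes 9 rose and 0 fell, 15 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.000393, adjusted p = 0.754 with an estimated correlation). The mitotic kinase genes CDKB1;1, CDKB1;2 and CDKB2;1 rose by 0.56 ± 0.12, 0.49 ± 0.11 and 0.43 ± 0.08. In the S phase list PCNA1 and PCNA2 rose (0.46 ± 0.14 and 0.44 ± 0.14) and 17 of 19 did not pass. The edgeR calls of PCNA1 and PCNA2 were lost without WT replicate 3 (adjusted p = 0.0757 and 0.0981) or 4 (0.0736 and 0.0917) and without ckx3 ckx5 replicate 3 (0.0541 and 0.0624) or 4 (0.0806 and 0.0671), and that of PCNA2 also without ckx3 ckx5 replicate 2 (0.0611). The S phase median was 0.29 (camera adjusted p = 0.0115, adjusted p = 0.764 with an estimated correlation, 0.0591 without WT replicate 4). By edgeR 0 S phase genes passed when adjusted over the list alone, 9 had an unadjusted p under 0.05, and over all genes DESeq2 called 4 and limma-voom 5. The CDK inhibitors had 2 of 20 up and 3 down, 4 adjusted over the list alone (camera adjusted p = 0.953), with KRP1 at -1 ± 0.23 and KRP7 at 0.52 ± 0.17. The other 2 that fell were the SIAMESE-RELATED genes AT1G10690 (-0.77 ± 0.20) and AT1G08180 (-0.43 ± 0.12). The edgeR call of AT1G08180 was lost without WT replicate 3 (adjusted p = 0.0693) or 4 (0.0621), without ckx3 ckx5 replicate 3 (0.0548) and with only the 2 groups in the model (0.0577). Against WT replicates 1 and 2 alone neither gene passed (0.125 for AT1G10690 and 0.394 for AT1G08180). Meristem genes had 4 of 27 up and 7 down, 14 adjusted over the list alone (camera adjusted p = 0.567), with RAX2, a regulator of axillary meristem formation, at -0.92 ± 0.15, ATH1 at 0.43 ± 0.08 and SPL9 at 0.55 ± 0.10. Of 20 flowering genes 8 rose and 3 fell, 14 adjusted over the list alone (camera adjusted p = 0.0916). The list's mean log2 CPM was 2.08 in ckx3 ckx5 replicate 4 and 2.66 to 2.76 in the other 3. The floral identity gene LFY rose by 0.68 ± 0.16 and TFL1 by 0.58 ± 0.13, while TSF, a relative of FT, was at -4.40 ± 0.63 (-5.10 without ckx3 ckx5 replicate 1).

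The salicylic acid list fell as a whole in the libraries labelled ckx3 ckx5 (0 of 15 rose, 15 fell, 15 adjusted over the list alone, median -1.70, mean -1.89, camera adjusted p = 1.13e-20, adjusted p = 0.0577 with an estimated correlation). EDS1 and WRKY54 changed by -1.03 ± 0.10 and -1.62 ± 0.11. The wounding and touch markers fell likewise (0 of 6 rose, 5 fell, 6 adjusted over the list alone, camera adjusted p = 0.00224, adjusted p = 0.569 with an estimated correlation), with WRKY33 at -1.63 ± 0.19 and WRKY40 at -2.90 ± 0.45. Of 15 jasmonate genes 2 rose and 4 fell, 6 adjusted over the list alone (camera adjusted p = 0.346), with LOX4 at -1.62 ± 0.33, LOX3 at -1.37 ± 0.33 (-0.69 without WT replicate 1) and the defensin gene PDF1.2 at -2.71 ± 0.54. Among markers of other tissue, 3 of 19 leaf photosynthesis genes fell and 0 rose, 3 adjusted over the list alone (camera adjusted p = 0.346). These were RCA (-0.83 ± 0.18), GAPA (-0.39 ± 0.12) and GAPB (-0.60 ± 0.18). The edgeR calls of GAPA and GAPB were lost without WT replicate 1 (adjusted p = 0.0575 and 0.0617) or 2 (0.0522 and 0.0506) and without ckx3 ckx5 replicate 1 (0.0569 and 0.0535) or 4 (0.0813 and 0.0639). XCP1 (0.43 ± 0.08) and XCP2 (0.32 ± 0.06) rose among 17 xylem genes and 0 fell, 2 adjusted over the list alone (camera adjusted p = 0.499). None of 4 root markers was called by edgeR (0 adjusted over the list alone), where 1 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. The leaf score of these libraries lay between those of WT replicates 4 and 2.

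The clock list had 6 genes up and 3 down of 9 measured, all 9 also adjusted over the list alone. PRR7, TOC1, GI, ELF4 and LUX rose by 0.46 ± 0.06, 0.50 ± 0.08, 0.97 ± 0.11, 1.68 ± 0.37 and 1.16 ± 0.09, and PRR9 changed by -0.63 ± 0.11. The median (0.50) and mean (0.21) of the clock list were positive while camera called it down (adjusted p = 0.0452, adjusted p = 0.569 with an estimated correlation). Without a filter camera gave the other direction (0.221), and the call was lost without ckx3 ckx5 replicate 1 (0.0537), 3 (0.0686) or 4 (0.142) and with only the 2 groups in the model (0.307). Outside the lists, the largest rises by the naming rule were MEE14 (2.60 ± 0.25), the chlorophyll synthesis gene PORB (2.46 ± 0.12), GRP7, a clock-controlled RNA-binding protein gene (2.30 ± 0.09), LZF1 (2.19 ± 0.11) and CCL (2.1 ± 0.22). The largest falls included ELIP1, an early light-induced gene (-3.60 ± 0.88), BBX32 (-2.98 ± 0.17), the defensin gene PDF1.2c (-2.93 ± 0.53) and the amino acid transporter gene LHT7 (-2.75 ± 0.22). Without WT replicate 1 ELIP1 stood at -3. Against WT replicates 3 and 4 alone it stood at -1.36 (edgeR adjusted p = 0.27), and limma-voom gave it an adjusted p of 0.126.

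**Figure D2:**
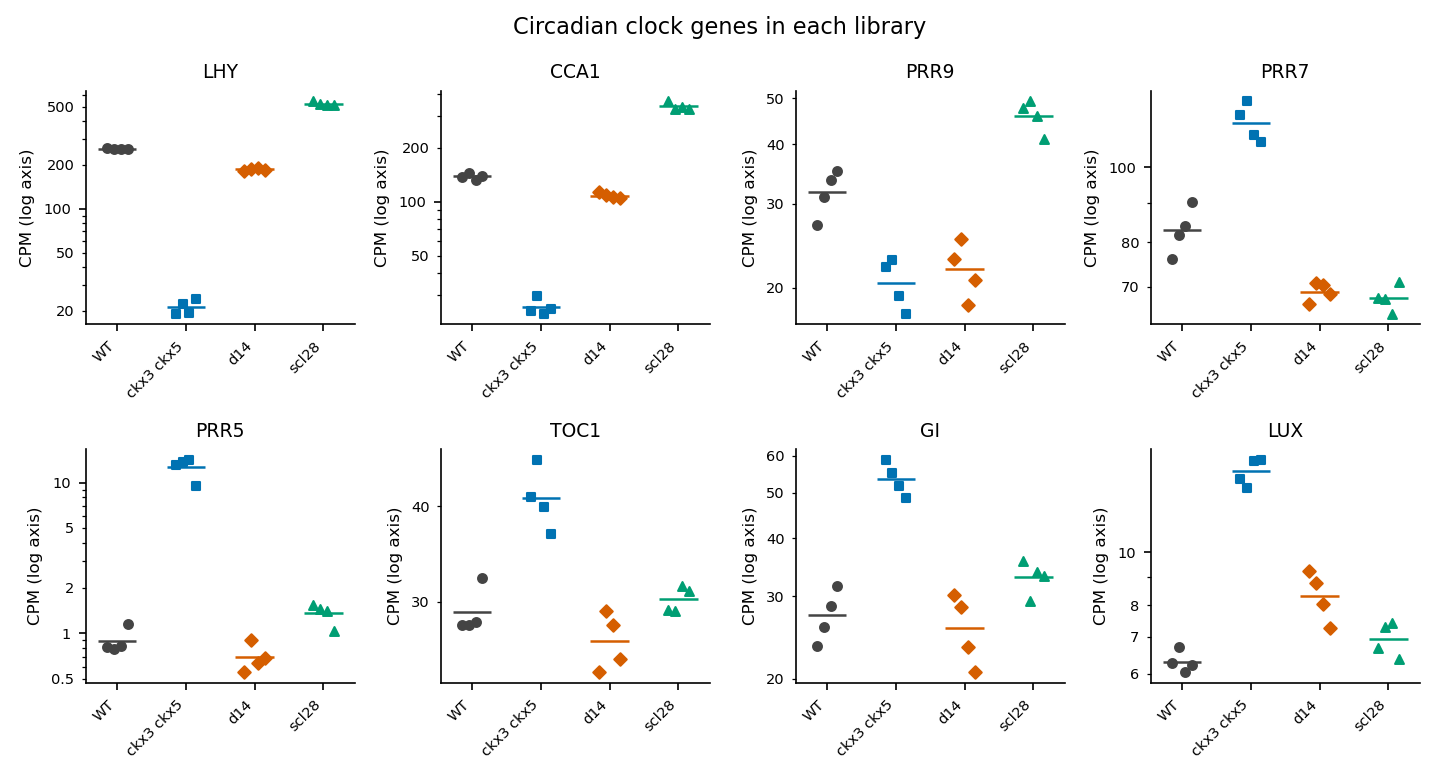
CPM of clock genes in each library on log axes, 1 point per library and a line at the mean of each genotype (n = 4). LHY lies at 256 to 260 CPM in WT, 19.1 to 24.3 in the libraries labelled ckx3 ckx5, 183 to 189 in d14-7 and 518 to 548 in scl28.

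In d14-7, which lacks the strigolactone receptor function and is known for extra branches, 8 of 9 bud dormancy genes were lower than in WT. BRC1 changed by -4.22 ± 0.27, and the homeodomain genes that act after it, HB21, HB40 and HB53, by -3.27 ± 0.36, -4.45 ± 0.27 and -3.25 ± 0.35. The strigolactone synthesis genes MAX3 and MAX4 rose by 3.83 ± 0.29 and 3.63 ± 0.15. Of 24 abscisic acid response genes 22 fell, while 23 of 25 G2/M genes and 14 of 19 S phase genes rose. The auxin synthesis genes YUC2 and YUC6 rose by 2.90 ± 0.35 and 1.90 ± 0.23. Of 20947 genes 8101 changed by edgeR, 3796 up and 4305 down, and 1022 of them at least 2-fold (315 up, 707 down). Without WT replicate 3 the count was 5234 and without WT replicate 4 it was 5026. It was 5034 with only the 2 groups in the model, 2195 with the leaf score as covariate and 2307 against WT replicates 1 and 2 alone.

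The bud dormancy list held its call in d14-7 with an estimated correlation (0 of 9 rose, 8 fell, 8 adjusted over the list alone, median -3.25, camera adjusted p = 7.38e-17, adjusted p = 0.0497 with an estimated correlation). NCED3, of abscisic acid synthesis, changed by -2.94 ± 0.41, DRM1 by -1.56 ± 0.26, DRM2 by -3.99 ± 0.42 and HIS1-3 by -3.23 ± 0.46, and BRC2 stood at 0.05 ± 0.16. Strigolactone and karrikin genes went both ways in d14-7 (4 of 15 rose, 7 fell, 11 adjusted over the list alone). D27 (1.27 ± 0.34) and LBO1 (1.16 ± 0.15), both of synthesis, rose with MAX3 and MAX4, while the repressor genes SMXL6, SMXL7 and SMXL8 changed by -1.15 ± 0.09, -1.43 ± 0.09 and -1.28 ± 0.10. Camera found no common direction for this list (adjusted p = 0.411), whose median was -0.46 and mean 0.24. Carbon starvation markers fell (0 of 17 rose, 13 fell, 14 adjusted over the list alone, camera adjusted p = 6.6e-07, adjusted p = 0.315 with an estimated correlation), with TPS10 at -1.05 ± 0.14, GDH2 at -0.77 ± 0.09 and EXL2 at -1.15 ± 0.18.

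**Figure D3:**
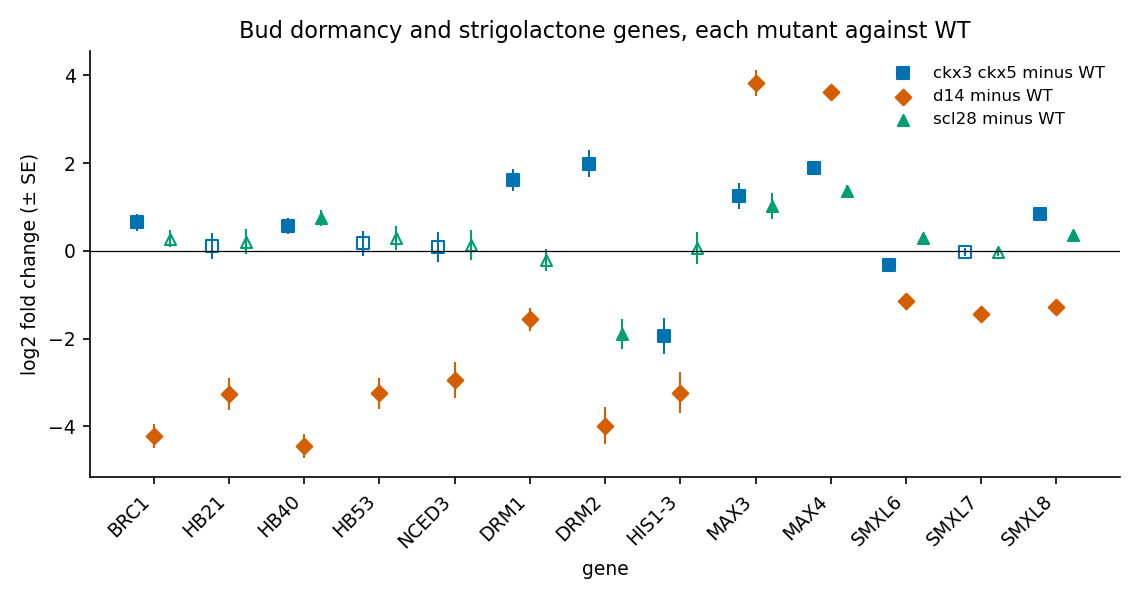
Log2 fold change against WT of 13 bud dormancy and strigolactone genes in the libraries labelled ckx3 ckx5, in d14-7 and in scl28, with standard error (n = 4 per group). Filled points passed an edgeR adjusted p of 0.05 and open points did not, and BRC1 stands at -4.22 in d14-7.

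Abscisic acid response fell as a list in d14-7 (0 of 24 rose, 22 fell, 23 adjusted over the list alone, camera adjusted p = 1.69e-14, adjusted p = 0.0986 with an estimated correlation), with LEA4-5 at -4.81 ± 0.43, HB12 at -1.21 ± 0.13 and KIN2 at -1.52 ± 0.17. Auxin transport and synthesis rose (11 of 17 rose, 2 fell, 14 adjusted over the list alone, camera adjusted p = 2.33e-05, adjusted p = 0.0497 with an estimated correlation), with TAA1 at 1.30 ± 0.17 and the carriers PIN4 at 0.86 ± 0.12 and LAX3 at -0.33 ± 0.10. Auxin response had 5 of 13 up and 1 down, 6 adjusted over the list alone (camera adjusted p = 0.0357, adjusted p = 0.551 with an estimated correlation), with IAA29 at 3.59 ± 0.49, GH3.1 at 1.25 ± 0.27 and GH3.5 at -1.44 ± 0.27. The camera call for auxin response was lost without WT replicate 1 (0.303), without d14-7 replicate 3 (0.0783) or 4 (0.101) and with the stricter filter (0.0872). The edgeR calls of GH3.1 and GH3.5 were lost with the leaf score as covariate (adjusted p = 0.0662 and 0.135) and against WT replicates 1 and 2 alone (0.0541 and 0.0738). Gibberellin genes fell (1 of 16 rose, 9 fell, 10 adjusted over the list alone, camera adjusted p = 0.000692, adjusted p = 0.0986 with an estimated correlation), among them the inactivation gene GA2OX2 at -1.67 ± 0.22, the synthesis gene GA3OX1 at -0.87 ± 0.12 and SCL3 at -0.55 ± 0.08. Type-A response regulators had 4 of 8 up and 0 down, 6 adjusted over the list alone (camera adjusted p = 0.00564, adjusted p = 0.423 with an estimated correlation, 0.167 with the leaf score as covariate), with ARR8 at 0.36 ± 0.07 and ARR5 at 0.41 ± 0.13. The other cytokinin-induced genes had 3 of 9 up and 2 down, 5 adjusted over the list alone (camera adjusted p = 0.286), with CYP735A2 at 1.01 ± 0.23 and LBD3 at -1.35 ± 0.17. Cytokinin synthesis and breakdown had 7 of 21 up and 4 down, 11 adjusted over the list alone, and CKX1 stood at -2.14 ± 0.11. Camera placed that list down without a call (adjusted p = 0.824) while its median (0.08) and mean (0.05) were positive.

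The G2/M list rose in d14-7 (23 of 25 rose, 0 fell, 24 adjusted over the list alone, median 0.58, camera adjusted p = 4.36e-10, adjusted p = 0.336 with an estimated correlation), with EDE1 at 0.67 ± 0.11 and CDC20.2 at 0.67 ± 0.12. So did the S phase list (14 of 19 rose, 0 fell, 18 adjusted over the list alone, camera adjusted p = 6.76e-06, adjusted p = 0.423 with an estimated correlation), with ICU2 at 0.64 ± 0.12. CDK inhibitors had 5 of 20 up and 4 down, 9 adjusted over the list alone (camera adjusted p = 0.891), with KRP2 at -0.93 ± 0.12. Meristem genes fell (2 of 27 rose, 11 fell, 16 adjusted over the list alone, camera adjusted p = 0.00462, adjusted p = 0.336 with an estimated correlation), with WRKY71 at -2.45 ± 0.40, LOB at -0.86 ± 0.10 and RAX2 at -0.95 ± 0.15. Flowering genes had 2 of 20 up and 5 down, 7 adjusted over the list alone (camera adjusted p = 0.313, median 0.01, mean -0.16), with TSF at -3.60 ± 0.59 (-4.45 without d14-7 replicate 1), TFL1 at -1.10 ± 0.14 and FLC at -0.97 ± 0.16.

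Leaf photosynthesis genes moved with these groups in d14-7: 9 of 19 rose and 0 fell, 10 adjusted over the list alone (camera adjusted p = 0.000191, adjusted p = 0.537 with an estimated correlation), with CAB2 at 1.00 ± 0.24 and LHCA3 at 0.35 ± 0.11. The leaf list is the covariate itself, and with it camera gave 0.833. Against WT replicates 1 and 2 alone CAB2 stood at 0.57 (edgeR adjusted p = 0.0826). Salicylic acid genes fell (0 of 15 rose, 9 fell, 12 adjusted over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.33 with an estimated correlation), with PR1 at -2.97 ± 0.40 and PAD4 at -0.83 ± 0.14. With the leaf score as covariate 4 of the 15 fell, and against WT replicates 1 and 2 alone 5. Jasmonate genes had 5 of 15 up and 1 down, 7 adjusted over the list alone (camera adjusted p = 0.0335, adjusted p = 0.57 with an estimated correlation), with PDF1.2 at 2.32 ± 0.51 and JAZ7 at -1.26 ± 0.46. Their camera call was lost without WT replicate 2 (0.125) or 4 (0.0686), without d14-7 replicate 2 (0.083) and with the leaf score as covariate (0.426). Xylem genes had 5 of 17 up and 1 down, 6 adjusted over the list alone, with XCP1 at 0.46 ± 0.08 and NST1 at -1.06 ± 0.37. Camera gave the xylem list an adjusted p of 0.0321 (adjusted p = 0.57 with an estimated correlation), which was lost without WT replicate 1 (0.195) or 2 (0.099) or d14-7 replicate 1 (0.0858). Of 4 root markers PYK10 rose (0.94 ± 0.15), also adjusted over the list alone, and 0 fell.

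Among wounding markers WRKY40 fell by 1.14 (SE 0.40) and 5 of 6 did not pass (camera adjusted p = 0.176). The edgeR call of WRKY40 was lost without WT replicate 1 (adjusted p = 0.119), 3 (0.072) or 4 (0.0903) or d14-7 replicate 1 (0.0892), 2 (0.0993) or 4 (0.0629). Adjusted over the list alone, 0 passed by edgeR, 1 had an unadjusted p under 0.05, and over all genes DESeq2 called 1 and limma-voom 0. Clock genes had 1 of 9 up and 4 down in d14-7, 5 adjusted over the list alone (camera adjusted p = 0.0704), with CCA1 at -0.36 ± 0.07, LHY at -0.47 ± 0.07 and LUX at 0.40 ± 0.09. Outside the lists, UMAMIT14, an amino acid exporter gene, changed by -4.67 ± 0.38, GASA1 by -3.37 ± 0.28 and ACA1 by -2.55 ± 0.15, and DIN11 and ATCSLA15 rose by 2 ± 0.36 and 1.87 ± 0.32.

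In scl28, as in the other mutants, salicylic acid genes were lower and G2/M genes higher than in the same WT. PR1 changed by -4.52 ± 0.44, and all 15 measured members of its list fell. Of 25 G2/M genes 17 rose (9 in ckx3 ckx5, 23 in the d14 mutant), among them CDKB1;1 at 0.66 ± 0.12. Of 20 CDK inhibitors 5 rose and 5, all SIAMESE-RELATED genes, a family SCL28 is known to activate, fell. CCA1 and LHY rose by 1.30 ± 0.07 and 1.03 ± 0.07. Of 20947 genes 4155 changed by edgeR, 1949 up and 2206 down, and 855 of them at least 2-fold (106 up, 749 down). The count was 2221 with only the 2 groups in the model, 7253 with the leaf score as covariate and 7234 against WT replicates 3 and 4 alone. These plants were harvested 25 days after sowing and WT 23, so age and genotype differ together.

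The CDK inhibitors went both ways in scl28 (5 of 20 rose, 5 fell, 12 adjusted over the list alone, camera adjusted p = 0.428), with a positive median (0.06) and a negative mean (-0.13). The 5 that fell were SIAMESE-RELATED genes without a symbol in the annotation: AT1G08180 (-1.59 ± 0.13), AT1G51355 (-1.34 ± 0.17), AT5G59360 (-1.21 ± 0.18), AT5G40460 (-1.11 ± 0.21) and AT1G10690 (-0.57 ± 0.19). Of these, AT1G08180 and AT1G10690 also fell in the libraries labelled ckx3 ckx5. KRP5, KRP3, KRP7 and KRP2 of the other family of inhibitors rose by 0.75 ± 0.10, 0.90 ± 0.17, 0.67 ± 0.17 and 0.36 ± 0.11, as did the SIAMESE-RELATED gene AT2G28330 (0.43 ± 0.14). The G2/M list rose (17 of 25 rose, 0 fell, 24 adjusted over the list alone, median 0.46, camera adjusted p = 1.99e-09, adjusted p = 0.478 with an estimated correlation). In the S phase list CYCA3;1 rose (0.57 ± 0.17), 0 fell and 18 of 19 did not pass, with a median of 0.30 (camera adjusted p = 0.0016, adjusted p = 0.604 with an estimated correlation). The edgeR call of CYCA3;1 was lost without WT replicate 3 (adjusted p = 0.0773) or 4 (0.072) or scl28 replicate 2 (0.0695) or 3 (0.0657). Adjusted over the list alone, 0 S phase genes passed by edgeR, 8 had an unadjusted p under 0.05, and over all genes DESeq2 called 2 and limma-voom 1.

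Of 9 bud dormancy genes HB40 rose (0.74 ± 0.18) and DRM2 fell (-1.89 ± 0.34), also 2 adjusted over the list alone (camera adjusted p = 0.684, median 0.14, mean -0.03), and BRC1 stood at 0.28 ± 0.19. Strigolactone and karrikin genes had 5 of 15 up and 0 down, 5 adjusted over the list alone, with MAX4 at 1.36 ± 0.15, MAX3 at 1.03 ± 0.30 and AT3G24420 (DLK2) at 1.07 ± 0.26. Their camera adjusted p of 0.0331 (adjusted p = 0.478 with an estimated correlation) was lost without WT replicate 1 (0.191) or 2 (0.0529) and with the leaf score as covariate (0.327). Meristem genes had 7 of 27 up and 0 down, 7 adjusted over the list alone, with the boundary gene CUC3 at 1.24 ± 0.14, ATH1 at 0.57 ± 0.08 and KNAT2 at 0.48 ± 0.11. Camera gave the meristem list 0.0308 as adjusted p (adjusted p = 0.521 with an estimated correlation), lost without WT replicate 1 (0.181), scl28 replicate 3 (0.0722) or 4 (0.058) and with the leaf score as covariate (0.386). Flowering genes had 4 of 20 up and 0 down, 4 adjusted over the list alone: AP1 (1.06 ± 0.28), LFY (0.60 ± 0.16), SPL4 (0.49 ± 0.12) and SVP (0.18 ± 0.06). The edgeR call of LFY was lost without scl28 replicate 3 (adjusted p = 0.0604). Camera gave the flowering list 0.0331 as adjusted p (adjusted p = 0.521 with an estimated correlation), lost without WT replicate 1 (0.113) or 2 (0.0591), scl28 replicate 2 (0.0854) or 3 (0.0727) and with the leaf score as covariate (0.0965). Carbon starvation markers fell (0 of 17 rose, 8 fell, 10 adjusted over the list alone, camera adjusted p = 1.79e-05, adjusted p = 0.478 with an estimated correlation), with BGAL4 at -1.90 ± 0.23 and ASN1 at -1.86 ± 0.31.

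No cytokinin or auxin list was called in scl28. ARR9 rose (0.53 ± 0.12) among 8 type-A response regulators with 0 down, 1 adjusted over the list alone (camera adjusted p = 0.496). AHK4 rose (0.33 ± 0.10) among 9 other cytokinin-induced genes with 0 down, 1 adjusted over the list alone (camera adjusted p = 0.864, median 0.02, mean -0.03). CKX6 (0.46 ± 0.09) and IPT3 (-0.63 ± 0.13) were called among 21 genes of cytokinin synthesis and breakdown, 2 adjusted over the list alone (camera adjusted p = 0.966, median 0.06, mean -0.04). Of 13 auxin response genes IAA19 (-0.81 ± 0.22) and GH3.3 (-0.79 ± 0.13) fell and 0 rose, 2 adjusted over the list alone (camera adjusted p = 0.645). Auxin transport had 2 of 17 up and 2 down, 4 adjusted over the list alone (camera adjusted p = 0.645), with the auxin transport regulator PID at 0.48 ± 0.08 and LAX2 at -0.25 ± 0.07. Gibberellin genes GASA4 (0.50 ± 0.13), SCL3 (0.29 ± 0.08) and GID1A (0.30 ± 0.08) rose among 16 with 0 down, 3 adjusted over the list alone (camera adjusted p = 0.619). Abscisic acid response had 6 of 24 up and 4 down, 11 adjusted over the list alone (camera adjusted p = 0.103), with KIN2 at 1.22 ± 0.17 and HB12 at 0.82 ± 0.13. Leaving out single libraries ended the edgeR calls of AHK4 (WT replicate 3, adjusted p = 0.0847, WT replicate 4, 0.0811, and scl28 replicate 1, 0.0975), IAA19 (WT replicate 3, 0.0648, WT replicate 4, 0.0612, scl28 replicate 1, 0.0584, and scl28 replicate 2, 0.0531) and GID1A (WT replicate 2, 0.0533).

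The defence lists fell in scl28. Salicylic acid genes kept their call with an estimated correlation (0 of 15 rose, 15 fell, 15 adjusted over the list alone, median -1.36, camera adjusted p = 2.91e-20, adjusted p = 0.0289 with an estimated correlation), with SARD1 at -1.32 ± 0.16 and WRKY38 at -1.99 ± 0.24. Jasmonate genes fell as a list (0 of 15 rose, 8 fell, 10 adjusted over the list alone, camera adjusted p = 5.55e-05, adjusted p = 0.478 with an estimated correlation), with JAZ1 at -1.03 ± 0.21, LOX4 at -1.71 ± 0.33 and PDF1.2 at -4.02 ± 0.59 (-4.86 without scl28 replicate 2). Of 6 wounding markers WRKY33 (-1.36 ± 0.19) and WRKY40 (-1.51 ± 0.41) fell and 0 rose, 2 adjusted over the list alone (camera adjusted p = 0.0721). Leaf photosynthesis genes LHCA2 (-0.37 ± 0.10), LHCA1 (-0.40 ± 0.14) and CAB3 (-0.48 ± 0.16) fell among 19 with 0 up, 6 adjusted over the list alone. Their camera adjusted p of 0.00164 (adjusted p = 0.604 with an estimated correlation) was lost without WT replicate 1 (0.142), and was 0.902 with the leaf score as covariate. Of 17 xylem genes LAC17 (-0.45 ± 0.10), XCP1 (-0.35 ± 0.08) and MYB83 (-0.87 ± 0.28) fell and 0 rose, 3 adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.604 with an estimated correlation, lost without WT replicate 4 at 0.127 and without scl28 replicate 2 at 0.152). Of 4 root markers PYK10 (-0.76 ± 0.15) and LRX1 (-1.66 ± 0.51) fell and 0 rose, 2 adjusted over the list alone.

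Single libraries decided some of these edgeR calls in scl28. That of WRKY40 was lost without WT replicate 1 (adjusted p = 0.0519), scl28 replicate 1 (0.0501) or 3 (0.0569). Those of CAB3 and LHCA1 were lost without WT replicate 1 (0.105 and 0.112) or 2 (0.0767 and 0.0869) and without scl28 replicate 1 (0.0932 and 0.0965), 3 (0.118 and 0.13) or 4 (0.101 and 0.104). The call of MYB83 was lost without WT replicate 2 (0.0545), 3 (0.0543) or 4 (0.114) and scl28 replicate 1 (0.101), 2 (0.103) or 3 (0.0926), and that of LRX1 without WT replicate 3 (0.0838) or 4 (0.105) and scl28 replicate 1 (0.0782), 2 (0.0725), 3 (0.0509) or 4 (0.0544).

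**Figure D4:**
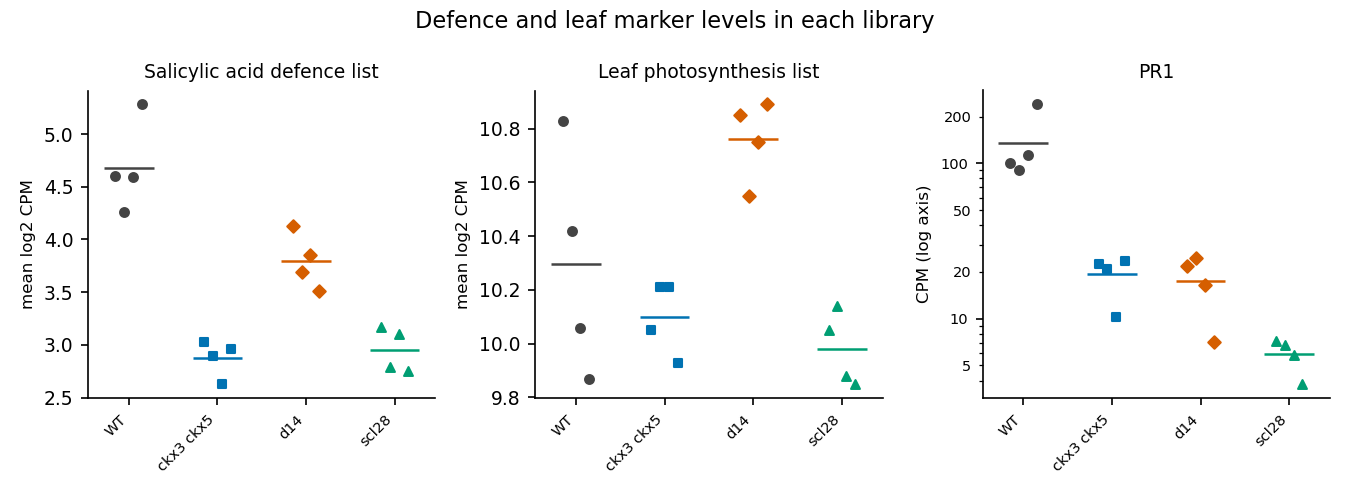
Mean log2 CPM of the salicylic acid defence genes, mean log2 CPM of the leaf genes (the leaf score) and CPM of PR1 in 3 panels, 1 point per library and a line at the mean of each genotype (n = 4). WT lies at 4.26 to 5.28 in the defence panel, above the libraries labelled ckx3 ckx5 (2.63 to 3.03), d14-7 (3.51 to 4.13) and scl28 (2.75 to 3.17), while its leaf scores run from 9.87 to 10.83.

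Clock genes rose as a list in scl28 and kept the call with an estimated correlation (5 of 9 rose, 1 fell, 7 adjusted over the list alone, median 0.53, camera adjusted p = 2.94e-08, adjusted p = 0.0275 with an estimated correlation). ELF4, PRR5 and PRR9 rose by 1.64 ± 0.37, 0.58 ± 0.20 and 0.53 ± 0.11 and PRR7 fell by 0.29 (SE 0.06). Outside the lists, BGLU47 rose by 2.31 ± 0.15, COL2 by 1.62 ± 0.09, the morning gene RVE1 by 1.36 ± 0.10 and CXE13 by 1.26 ± 0.20. MRD1 (chromosome 1, 19963047 to 19964712) was nearly without counts in scl28, at 0.119 CPM (15 counts) against 59.5 ± 3.07 CPM in WT. It changed by -8.95 (edgeR adjusted p = 2.18e-15, -9.61 without scl28 replicate 4). The defensin genes PDF1.2c and PDF1.2, FAMT and the peroxidase gene Prx37 changed by -4.04 ± 0.58, -4.02 ± 0.59, -3.97 ± 0.79 and -2.96 ± 0.28. Without scl28 replicate 2 PDF1.2c and PDF1.2 stood at -4.90 and -4.86, and without WT replicate 1 FAMT stood at -2.76. Without WT replicate 1 the number of lists called by camera was 7 in place of 11.

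The scl28 libraries were also compared with the libraries labelled ckx3 ckx5, since both genotypes are named for fewer branches. LHY, CCA1 and RVE8 were higher in scl28 by 4.63 ± 0.08, 3.72 ± 0.08 and 2.93 ± 0.06, and PRR5 was lower by a log2 change of -3.21 ± 0.18. IPT7 had 86 counts in scl28 and 3 in ckx3 ckx5 (27.6-fold, 95% counting interval 9.15 to 137), whereas 4 of 8 type-A response regulators and 12 of 17 carbon starvation markers were lower. No G2/M gene and no S phase gene differed. Of 20947 genes 5169 differed by edgeR, 2752 higher and 2417 lower in scl28, and 951 of them at least 2-fold (441 higher, 510 lower). Harvest day differs here too, the hour may differ, and the direction rests on labels that CKX3 goes against.

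Among hormone lists, type-A response regulators were lower in scl28 (0 of 8 higher, 4 lower, 4 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.717 with an estimated correlation), with ARR5, ARR6 and ARR4 at -0.91 ± 0.13, -0.93 ± 0.16 and -0.85 ± 0.17. Of the 9 other cytokinin-induced genes 0 were higher and 3 lower, 4 adjusted over the list alone (camera adjusted p = 0.465), with CKX4 at -1.01 ± 0.26. Cytokinin synthesis and breakdown had 2 of 21 higher and 3 lower, 5 adjusted over the list alone (camera adjusted p = 0.79), with CKX7 at 0.46 ± 0.07 and CKX6 at -0.48 ± 0.09. Auxin response was lower (0 of 13 higher, 5 lower, 5 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.717 with an estimated correlation), with IAA1 at -1.02 ± 0.17, IAA19 at -1.26 ± 0.22 and GH3.3 at -0.95 ± 0.13. Auxin transport had 4 of 17 higher and 6 lower, 11 adjusted over the list alone (camera adjusted p = 0.465), with PID at 0.83 ± 0.08 and LAX1 at -0.71 ± 0.11. Gibberellin genes had 1 of 16 higher and 5 lower, 8 adjusted over the list alone (camera adjusted p = 0.0687), with SCL3 at 0.94 ± 0.08, GA2OX1 at -2.17 ± 0.22 and GASA6 at -1.66 ± 0.16. Abscisic acid response was higher (13 of 24 higher, 4 lower, 17 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.717 with an estimated correlation), with HB12 at 1.79 ± 0.13 and HAB1 at 1.07 ± 0.07.

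Strigolactone and karrikin genes had 5 of 15 higher and 4 lower, 10 adjusted over the list alone (camera adjusted p = 0.465, median -0.01, mean 0.11), with MAX1 at 1.18 ± 0.13, SMXL6 at 0.62 ± 0.08 and SMXL8 at -0.47 ± 0.10. Of 9 bud dormancy genes HIS1-3 was higher (1.99 ± 0.41), and DRM2 (-3.88 ± 0.34) and DRM1 (-1.82 ± 0.25) were lower, 3 adjusted over the list alone (camera adjusted p = 0.233, median 0.05, mean -0.43). BRC1 stood at -0.37 ± 0.19. Carbon starvation markers were lower in scl28 (1 of 17 higher, 12 lower, 13 adjusted over the list alone, camera adjusted p = 1.67e-06, adjusted p = 0.717 with an estimated correlation), with DIN10 at -2.82 ± 0.26, TPS11 at -1.35 ± 0.16 and GDH2 at -0.78 ± 0.09. Of 25 G2/M genes 0 were called by edgeR, 0 adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (camera adjusted p = 0.465). Of 19 S phase genes 0 were called by edgeR, also adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 (camera adjusted p = 0.889, median 0.02, mean -0.02). CDK inhibitors had 4 of 20 higher and 6 lower, 12 adjusted over the list alone (camera adjusted p = 0.465, median 0.14, mean -0.14), with AT1G51355 at -1.62 ± 0.17, AT5G59360 at -1.57 ± 0.18 and AT1G08180 at -1.16 ± 0.13. Meristem genes were higher (8 of 27 higher, 1 lower, 10 adjusted over the list alone, camera adjusted p = 0.0295, adjusted p = 0.717 with an estimated correlation, lost without scl28 replicate 1 at 0.056 and replicate 4 at 0.05), with CUC3 at 1.10 ± 0.14 and LOB at 0.71 ± 0.09.

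Flowering genes had 3 of 20 higher and 1 lower, 4 adjusted over the list alone (camera adjusted p = 0.967), with TSF at 3.19 ± 0.66 (3.88 without ckx3 ckx5 replicate 1), AGL24 at 0.51 ± 0.08 and SPL4 at 0.49 ± 0.12 higher and TFL1 at -0.40 ± 0.13. Salicylic acid genes had 4 of 15 higher and 1 lower, 5 adjusted over the list alone (camera adjusted p = 0.0987, median 0.22, mean -0.01), with WRKY70 at 1.22 ± 0.11, WRKY54 at 0.91 ± 0.11 and PR1 at -1.71 ± 0.42. Jasmonate genes had 0 of 15 higher and 5 lower, 6 adjusted over the list alone (camera adjusted p = 0.0544), with OPR3 at -0.54 ± 0.12 and VSP2 at -1.18 ± 0.26. Wounding markers had 3 of 6 higher and 0 lower, 3 adjusted over the list alone (camera adjusted p = 0.0987), with TCH2 at 0.96 ± 0.24. Leaf genes had 0 of 19 higher and 4 lower, 7 adjusted over the list alone (camera adjusted p = 0.208), with LHCA2 at -0.48 ± 0.10. Xylem genes were lower (1 of 17 higher, 3 lower, 4 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.744 with an estimated correlation, lost without scl28 replicate 2 at 0.0834), with XCP1 at -0.78 ± 0.08 and XCP2 at -0.48 ± 0.06. Of 4 root markers PYK10 was lower (-0.73 ± 0.15), 1 adjusted over the list alone, and 0 were higher.

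Clock genes had 3 of 9 higher and 5 lower in scl28 than in the libraries labelled ckx3 ckx5, 8 adjusted over the list alone. Camera called the list up (adjusted p = 1.99e-07, adjusted p = 0.0395 with an estimated correlation, 0.935 without a filter), with a negative median (-0.44) and a positive mean (0.37). Outside the lists ELIP1, BBX32 and COL2 were higher by 4.38 ± 0.88, 3.97 ± 0.17 and 3.83 ± 0.11. MRD1 (-9.16, -9.82 without scl28 replicate 4), CCL (-3.61 ± 0.24), the jasmonate synthesis gene AOC2 (-3.57 ± 0.61), MEE14 (-3.30 ± 0.26) and the expansin gene EXPA8 (-2.92 ± 0.28) were lower.

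**Figure D5:**
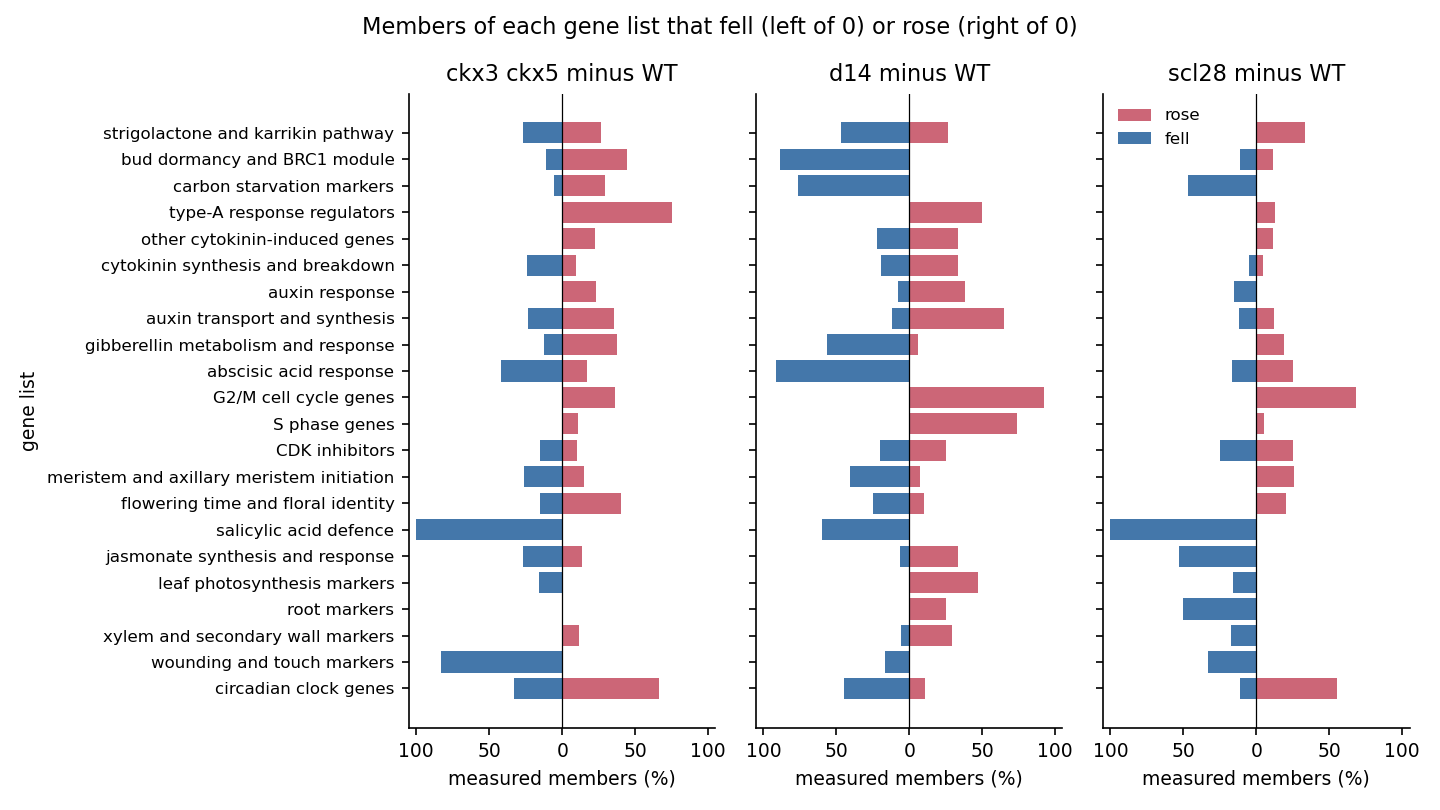
Percentage of the measured members of each of the 22 lists that rose (right) or fell (left) against WT at an edgeR adjusted p under 0.05, for the libraries labelled ckx3 ckx5, d14-7 and scl28. All 15 salicylic acid defence genes fell in the libraries labelled ckx3 ckx5 and in scl28, and 22 of 24 abscisic acid genes fell in d14-7.

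The libraries labelled ckx3 ckx5 and scl28 shared changes against WT. BGLU47 rose by 1.64 ± 0.15 and 2.31 ± 0.15 in them, ELF4 by 1.68 ± 0.37 and 1.64 ± 0.37, LSU3, a gene induced by low sulfur, by 1.99 ± 0.32 and 1.66 ± 0.32, and AT5G35935 by 2.07 ± 0.14 and 1.81 ± 0.14. The defensin genes PDF1.3 (-3.91 ± 0.46 and -4.62 ± 0.50) and PDF1.2b (-3.50 ± 0.47 and -3.82 ± 0.48) fell in both, and PDF1.3 in scl28 was at -5.24 without scl28 replicate 2. AT3G57700, of the protein kinase superfamily, had 0 counts in each library labelled ckx3 ckx5 and 31, 46, 47 and 91 in WT. In all, 1823 genes changed the same way in both (677 up, 1146 down), where independent lists give 618 (265 up, 353 down), and 418 changed in opposite directions against 612. Of 20 simulations of unchanged groups against the same WT libraries, 19 called 0 genes in at least 1 of the comparisons, so their overlap counts decide nothing. With separate WT libraries for each comparison the count ran from 739 to 1250 and the opposite count from 177 to 859. Without WT replicate 1 the count was 3134, without replicate 3 it was 1198 and without replicate 4 it was 1176. It was 1024 with only the compared groups in the model and 4230 with the leaf score. Against WT replicates 1 and 2 alone it was 1033, and against 3 and 4 alone 4738. The correlation of fold changes across genes, which are not independent replicates, was 0.50 (0.67 in the median simulation, 0.16 to 0.40 with separate WT libraries), and the covariance was 0.134 against a mean of 0.0318 and a highest value of 0.0979 simulated. With separate WT libraries it ran from 0.0517 to 0.116.

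Genes that went opposite ways in d14-7 and in the libraries labelled ckx3 ckx5 included DRM2 (-3.99 ± 0.42 and 1.99 ± 0.30), BGLU47 (-2.04 and 1.64), the cold-response factor gene DREB1A (-2.29 and 2.41), RbcX1 (-2.52 and 2.69), SNRK2.9 (-2.1 and 2.27) and the defensin gene PDF1.3 (3.84 and -3.91). Single libraries decided the edgeR calls of RbcX1 in d14-7 (without WT replicate 1, adjusted p = 0.0509, d14-7 replicate 2, 0.0629, and 4, 0.065) and of SNRK2.9 in d14-7 (without WT replicate 3, 0.0606, and 4, 0.427, d14-7 replicate 1, 0.0885, 2, 0.112, and 3, 0.0955). Against WT replicates 1 and 2 alone SNRK2.9 turned to 0.11 in d14-7. Its counts in the 4 WT libraries were 3, 1, 8 and 33. Without WT replicate 4 it stood at -0.76 and 3.60, and without d14-7 replicate 4 at -3.10 in d14-7. DREB1A was at -2.92 in d14-7 without d14-7 replicate 2. Opposite changes numbered 552 (213 up and 339 down in d14-7) where independent lists give 1193. Changes in the same direction numbered 2386 where they give 1206. Sharing WT libraries lowers the opposite count. Without WT replicate 3 the opposite count was 354. It was 311 with only the compared groups in the model, 301 with the leaf score and 248 against WT replicates 1 and 2 alone. Separate WT libraries gave 176 to 1082 opposite and 894 to 1285 the same way. The correlation across genes was 0.35 (0.59 in the median simulation, 0.05 to 0.31 with separate WT libraries), and the covariance 0.0993 against a mean of 0.032 and a highest value of 0.109 simulated. Only the simulation with 4832 calls exceeded it. With separate WT libraries it ran from 0.0178 to 0.0932.

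In d14-7 and scl28 the opposite changes included BGLU47 (-2.04 and 2.31), AT1G26790 (-1.49 and 1.87), AT3G27250 (-1.75 and 1.36), IDH-III (-1.60 and 1.30), AT5G35935 (-1.28 and 1.81), PDF1.3 (3.84 and -4.62) and AT3G16670 (3.73 and -5.46). The edgeR call of IDH-III in scl28 was lost without scl28 replicate 3 (adjusted p = 0.0597). Without WT replicate 1 AT3G16670 stood at 5.21 and -3.98. The call of AT3G16670 was lost in d14-7 against WT replicates 1 and 2 alone (0.0523) and in scl28 against WT replicates 3 and 4 alone (0.132). Without scl28 replicate 2 AT3G16670 was at -6.42 and PDF1.3 at -5.24 in scl28. Opposite changes numbered 596 (203 up and 393 down in d14-7) where independent lists give 801. The opposite count was 259 with only the compared groups in the model, 383 with the leaf score and 371 against WT replicates 3 and 4 alone. Changes in the same direction numbered 1215 where they give 806. Separate WT libraries gave 156 to 1409 opposite and 396 to 682 the same way. The correlation across genes was 0.17 (0.61 in the median simulation, -0.13 to 0.17 with separate WT libraries), and the covariance 0.0467 against a mean of 0.0307 and a highest value of 0.0893 simulated. It thus lay within the range of unchanged groups. With separate WT libraries it ran from -0.0469 to 0.0451.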

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

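The tests of explanations in this part, and the counts over other splits of the libraries, were chosen only after the results were seen. Within each genotype, the highest or lowest of the 4 libraries was compared with the other libraries, and 17 of 193 such checks (8.8%) found 1 library apart, where chance gives about 1 in 20.

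CKX3 RNA was higher in the libraries labelled ckx3 ckx5 than in WT, against the label. An exchange of the labels of WT and ckx3 ckx5 is argued against by scl28, where CKX3 lay -1.86 from the libraries labelled ckx3 ckx5 (edgeR adjusted p = 0.00919), because scl28 would then be expected near those libraries. A joint rise of CKX genes stays open: of the 5 other measured CKX genes, 2 rose (CKX1 and CKX6) and 1 fell (CKX7). A transcript started in or near an insertion stays open too, because CKX3 has 1 transcript model and no part of the locus could be set against another. The low counts of CKX3 in WT, highest in replicates 1 and 2, add to the doubt about the size of the rise.

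All 15 salicylic acid defence genes were lower in the libraries labelled ckx3 ckx5 and in scl28 than in WT. A single WT library with much defence RNA is argued against as the whole cause, since without WT replicate 4 at least 13 of the 15 still fell in each (14 and 13, and 9 in d14-7). A different share of leaf is argued against likewise, since with the leaf score as covariate 15 of 15 fell in both, with medians of -1.84 and -1.46, while in d14-7 4 fell in place of 9. A defence response of the WT plants unrelated to genotype cannot be told apart from an effect of the mutations, because each genotype was grown once: the lowest WT library lay 1.09 above the highest of those mutant libraries in mean log2 CPM of the list. Effects of mutation on defence, and on G2/M and histone genes raised over this WT, are thus hypotheses.

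All 9 clock genes differed between WT and the libraries labelled ckx3 ckx5. A later hour of harvest within the stated window may account for this, since 9 of 9 changed in the direction they take later in the morning, with LHY, CCA1 and PRR9 lower and the other 6 higher. Those directions were taken from general knowledge of the clock and written down after the changes had been seen, so the test is weak. A change of the clock in the genotype stays open too (LHY at -3.61), as the labels give no hour per library. This limit holds for every comparison.

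The count of genes called by edgeR for the libraries labelled ckx3 ckx5 against WT (6205) was reached by 1 of the 35 splits of the 8 libraries, the real one, and the highest of the others gave 837. For d14-7 against WT it was 1 of 35 (8101, highest other 6337) and for scl28 against WT 1 of 35 (4155, highest other 3388). For scl28 against ckx3 ckx5 it was 1 of 35 (5169, highest other 1). The least possible share is 1 of 35, so chance is not excluded. Of 20 simulated unchanged groups with the spread of ckx3 ckx5, 1 called 4832 genes against WT, and those with the spread of scl28 called at most 1. The splits with the highest other counts against WT each placed WT replicate 1 among the mutant libraries, which points to a structure within WT. The number of lists called by camera was reached by other splits: 9 of 35 gave at least the 9 lists of ckx3 ckx5 against WT (highest other 11), 3 of 35 the 14 lists of d14-7 (highest other 16), 4 of 35 the 11 lists of scl28 (highest other 11) and 14 of 35 the 7 lists of scl28 against ckx3 ckx5 (highest other 10). Chance is thus not excluded for the numbers of lists. Of 50 regroupings of the 16 libraries, 1, the real one, gave as many genes changed the same way in ckx3 ckx5 and scl28 (1823, highest other 68), in opposite directions in d14-7 and ckx3 ckx5 (552, highest other 0) and in opposite directions in d14-7 and scl28 (596, highest other 0). Of the others, 1, 0 and 0 held any such gene, so these cannot decide on chance. Both opposite counts lie below the 1193 and 801 of independent lists, but sharing WT lowers them.

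Single libraries stood apart from the rest of their group in the mean log2 CPM of 6 lists. The strigolactone list was at 3.60 in scl28 replicate 4 (3.73 to 3.74 in the others), the other cytokinin-induced genes at 3.40 in ckx3 ckx5 replicate 3 (3.25 to 3.27), the CDK inhibitors at 2.13 in WT replicate 3 (2.28 to 2.29), the meristem list at 3.15 in WT replicate 1 (3.39 to 3.40), the flowering list at 2.08 in ckx3 ckx5 replicate 4 (2.66 to 2.76) and the root markers at 0.99 in scl28 replicate 3 (1.11 to 1.13).

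Single libraries also stood apart in the CPM of named genes. In WT replicate 1, CKX5 was at 6.11 CPM (2.11 to 2.56 in the others), LZF1 at 8.81 CPM (6.17 to 6.45) and FAMT at 41.9 CPM (3.95 to 8.54). In WT replicate 4, PR1 was at 239 CPM (90.8 to 114) and CCL at 49.5 CPM (25.5 to 29.3). In ckx3 ckx5 replicate 4, CKX5 was at 4.25 CPM (2.18 to 2.47) and EXPA8 at 28.7 CPM (17.3 to 18.3). In scl28 replicate 1, D14 was at 37.5 CPM (40.1 to 40.2), LHY at 548 CPM (518 to 521) and Prx37 at 2.69 CPM (1.69 to 1.82), and in scl28 replicate 4 DIN10 was at 7.47 CPM (4.72 to 5.18).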

How the results depend on the processing

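The alternatives by leaf score, by WT libraries taken 2 at a time and by transcript models were chosen after the data had been seen, and the others were planned. Of 697 list tests under alternatives, 601 kept direction and side of the threshold, 95 lost the call and 1 turned, and 4 of 41 called lists kept it under every setting run. Of 7120 tests of 347 results of named genes (a gene in a comparison), 6743 kept direction and side, 323 lost the call, 37 gained one and 17 turned, and 253 results kept theirs under every setting run. For the losses and turns below the cause was not tested, except that thresholds of 0.01 and of 2-fold can only lower a count and smaller groups give less power.

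Genes called in the libraries labelled ckx3 ckx5 against WT numbered 3813 against WT replicates 1 and 2, 3526 at 0.01 and 1141 at 2-fold. For d14-7 they numbered 5034 with only the 2 groups in the model, 2195 with the leaf score, 2307 against WT replicates 1 and 2, 3928 at 0.01 and 1022 at 2-fold. For scl28 they numbered 2221 with only the 2 groups, 7253 with the leaf score, 7234 against WT replicates 3 and 4, 1983 at 0.01 and 855 at 2-fold, and for scl28 against ckx3 ckx5 3199 at 0.01 and 951 at 2-fold. Genes changed the same way in ckx3 ckx5 and scl28 numbered 1024 with only the compared groups, 4230 with the leaf score, 1033 against WT replicates 1 and 2, 4738 against WT replicates 3 and 4, 814 at 0.01 and 381 at 2-fold. Opposite changes of d14-7 and ckx3 ckx5 numbered 311, 301 and 248 with the compared groups, the leaf score and WT replicates 1 and 2, 192 at 0.01 and 40 at 2-fold. Those of d14-7 and scl28 numbered 259 with the compared groups, 383 with the leaf score, 371 against WT replicates 3 and 4, 195 at 0.01 and 44 at 2-fold. Lists called with an estimated correlation numbered 0, 2, 2 and 1 (ckx3 ckx5, d14-7 and scl28 against WT, and scl28 against ckx3 ckx5). The last comparison had 12 with only its groups in the model.

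Leaving out 1 library gave 4685 to 8346 genes for ckx3 ckx5, 5026 to 10342 for d14-7, 2881 to 5652 for scl28 and 4132 to 4891 for scl28 against ckx3 ckx5. The overlaps ran from 1176 to 3134, 354 to 560 and 401 to 560, and the lists from 7 to 10, 12 to 14, 7 to 11 and 6 to 10. The lower end for genes against WT came without WT replicate 3 or 4 and the upper end without WT replicate 1.

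Replicate numbers did not pair the libraries: deviations of libraries with the same replicate number correlated at -0.276 to 0.342 over 24 pairs, 4 of them over 0.1, and by the number in the library name at -0.276 to 0.189 over 16 pairs, 2 over 0.1. Of the 16 libraries, 4 correlated best with a library of their own number. With the replicate number as a block edgeR called 5881, 7837, 3889 and 4884 genes, overlaps of 1680, 530 and 544, and camera 8, 14, 11 and 9 lists. With the library number as a block it called 4762, 4906, 3274 and 3261 genes, overlaps of 1326, 351 and 297, and 7, 13, 9 and 8 lists. In the library-number block NRT2.1 turned to -0.04 between scl28 and ckx3 ckx5, and CKX3 stood at -1.90 with an adjusted p of 0.0833.

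The clock list turned upward without a filter in ckx3 ckx5 (camera adjusted p = 0.221). Of the named genes that turned, CKX3 and CKX5 did so most often. CKX5 in ckx3 ckx5 stood at 0.24 without WT replicate 1, 0.11 with the leaf score and 0.28 against WT replicates 3 and 4, and at -0.49 without ckx3 ckx5 replicate 4. In scl28 CKX5 stood at -0.03, -0.04 and -0.10 without WT replicates 2, 3 and 4, -0.10 without scl28 replicate 1, -0.32 against WT replicates 1 and 2 and 0.54 without WT replicate 1. CKX3 in d14-7 stood at -0.28 with the leaf score and -0.42 against WT replicates 1 and 2, and in scl28 at -0.32 against the latter. Against WT replicates 1 and 2, LRX1 (0.19), TCH4 (0.02), ZAT10 (0.19) and SNRK2.9 (0.11) turned in d14-7, and ZAT10 (0.21) in scl28. Depth limits CKX3: with 24334925 to 36735056 counts in a library, it had 2 to 65 counts. In general 1.5-fold changes were recovered for 50% to 62% of simulated genes.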

Other observations

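The tests by gene family in this part were chosen after the results were seen. Families are genes with the same product name in the annotation, and 124 with at least 15 measured members were tested with camera. Of 49 TIR-NBS-LRR genes, 35 fell in the libraries labelled ckx3 ckx5 (median -0.68, camera adjusted p = 2.45e-13, adjusted p = 0.496 with an estimated correlation) and 23 fell in scl28 (camera adjusted p = 4.43e-12, adjusted p = 0.572 with an estimated correlation). Of 24 CC-NBS-LRR genes, 19 fell in the libraries labelled ckx3 ckx5 (camera adjusted p = 9.04e-08, adjusted p = 0.372 with an estimated correlation) and 6 in scl28 (camera adjusted p = 0.0159, adjusted p = 0.62 with an estimated correlation). Of 30 histone genes, 17 rose in the libraries labelled ckx3 ckx5 (camera adjusted p = 0.000157, adjusted p = 0.878 with an estimated correlation), 18 in d14-7 (camera adjusted p = 0.00191, adjusted p = 0.915 with an estimated correlation) and 19 in scl28 (camera adjusted p = 1.07e-06, adjusted p = 0.62 with an estimated correlation).

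Of 41 MATE efflux genes 18 fell and 3 rose in the libraries labelled ckx3 ckx5 (camera adjusted p = 0.000232, adjusted p = 0.226 with an estimated correlation), and 15 fell and 2 rose in scl28 (camera adjusted p = 0.00391, adjusted p = 0.497 with an estimated correlation). In d14-7, 35 of 185 pentatricopeptide repeat genes rose and 0 fell, where 3796 of all 20947 genes rose and 4305 fell (camera adjusted p = 0.00191, adjusted p = 0.915 with an estimated correlation). Between scl28 and the libraries labelled ckx3 ckx5, 14 of 61 Homeodomain-like genes, a family that holds LHY and RVE8, were higher and 4 lower (camera adjusted p = 1e-06, adjusted p = 0.00543 with an estimated correlation).

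Some genes were nearly without counts in 1 or 2 of the genotypes, and these were chosen after their values were seen. MRD1 had 15 counts over all 4 scl28 libraries and lay at 57.6 to 72.3 CPM in the other mutants. HEI10 (chromosome 1, 19963267 to 19966952), which overlaps most of MRD1, changed by -1.22 ± 0.13 in scl28 (edgeR adjusted p = 1.21e-05), and reads of the overlap cannot be assigned to either gene. AT1G27565 (chromosome 1, 9574550 to 9575189) had 3 counts over the 4 d14-7 libraries and 10 over the libraries labelled ckx3 ckx5, and was at 12.2 ± 0.627 CPM (SD, n = 4) in WT and at up to 7.6 CPM in scl28. AT3G57700 (chromosome 3, 21384917 to 21385939) lies within AT3G57710. It had 0 counts in each library labelled ckx3 ckx5, which allows up to 3 counts in each, and 16, 19, 19 and 33 counts in d14-7. In scl28 it had 9 counts in replicate 3 and 0 in the others.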
